A study of Drosophila melanogaster with 13 samples.

How the data were processed

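RNA was measured in 13 libraries of GFP-labelled neurons sorted by hand from fly brains: 4 pools of TRH-Gal4 cells, 1 pool of sNPFR-Gal4 cells and 8 single sNPFR-Gal4 cells. Pools and cells are named by the numbers in their labels. Per the labels' protocols, pools held 15 to 60 cells, cDNA was made with the SMART-Seq v4 kit with 12 PCR cycles for pools and 17 for single cells, and libraries with the Nextera XT kit. PCR copies cannot be told from molecules without molecular identifiers. Neither kit marks strand, so overlapping genes on opposite strands are uncertain.

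The authors' deposited counts are whole reads per gene for 17737 genes. Per the submitters' processing notes, STAR, edgeR and the BDGP6 genome build were used, with no versions. The counting tool, annotation release and strand setting are not given in the sources used here. The authors also deposited a normalized table, treated here as signal: 100% of its values were whole reads times 1 constant per library, within a relative tolerance of 0.001, and it lists the 6445 genes at 1 CPM or more in at least 3 of 13 libraries. The count table carries the same reads, so the count test was run on it. 1 column of per-sample values matching no sample in the sources used was not used. Groups came from the labels. Gene symbols were matched by identifier to the reference names for 17599 genes, of which 820 have another current symbol. Coordinates are from the BDGP6 annotation of Ensembl release 115.

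Depth ran from 3.38 to 68.0 M reads. A count of 0 allows up to 3 reads, which is 0.0535 CPM in the sNPFR pool. Cell 7 gave 52.7% of the 129.1 M summed reads of the cells.

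The 4 TRH pools were tested against 2 sNPFR units, the pool and the summed counts of the 8 cells, with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg threshold 0.05). Residual degrees of freedom were 4. Gene lists, 35 in all and fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry. At the preset correlation 11 of 25 tested lists passed, 4 higher in TRH. With an estimated correlation 0 passed (lowest adjusted p = 0.354). Fry passed 10, in part other lists: the 4 higher in TRH by camera and, of those higher in sNPFR, acetylcholine receptors (adjusted p = 0.00435). Fry did not pass channels (adjusted p = 0.0517), cholinergic (0.169), general neuronal (0.293), heat shock (0.512), ribosomal protein (0.885) or oxidative phosphorylation genes (0.1615). In 6 of the 25 lists the sign of the median and the direction of camera differed, since camera compares a list with all other genes. Groups, tests, lists and 25 of 28 alternatives for the comparison of groups were set before the data were examined, and 3 were chosen after seeing the data.

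Named genes followed a rule fixed in advance: transmitter genes, serotonin receptors, sNPF and sNPF-R whatever their values; the 10 genes per direction with the largest fold change past the threshold, a mean of at least 50 CPM in the higher group and no overlap between groups; up to 4 members of each other list with the smallest p; and the 5 most abundant genes of the TRH pools and of the cells. In single cells the rule also took any neuropeptide gene at 100 CPM or more in a cell. Dsk, Orcokinin, Dh31, CG12239, ninaE, Arr1, Arr2, dimm, repo and nrv2 are named outside the rule, after their values were seen.

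In single cells a gene counted as present at 10 CPM or more, and no cell was assigned a type. Alternatives were DESeq2 1.42.0, limma-voom, limma on the deposited CPM, other scalings and filters, each sNPFR unit alone, and each TRH pool or cell left out. Library similarity and detection were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. The test was run on simulated counts for 7426 genes with 200 changed: it recovered 33 of 99 genes changed 64-fold and 2 of 100 changed 8-fold, called 1 unchanged gene and gave 0 wrong signs, so a gene that did not pass is not shown to be unchanged. The simulated units were independent draws without a handling difference or shared reads. The rate of false calls in the real data is therefore not measured by them.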

Results

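The data were read counts per gene from GFP-labelled neurons picked by hand from brains of the fruit fly Drosophila melanogaster. Cells were labelled through either of 2 drivers. TRH-Gal4 is named for tryptophan hydroxylase, the enzyme that commits tryptophan to serotonin in neurons. sNPFR-Gal4 is named for the receptor of short neuropeptide F. The TRH-Gal4 group held 4 pools of cells, with 8.72 to 15.6 M reads each. The sNPFR-Gal4 samples were 1 pool, with 56.1 M reads, and 8 single cells, with 3.38 to 68.0 M reads. The labels name no animals, so cells were not counted as replicates. The sNPFR pool and the summed reads of the 8 cells entered the tests as 2 units against the 4 TRH pools, and p-values measure only the spread between these samples. TRH-Gal4 brains were dissociated and sNPFR-Gal4 brains were pinned, so tissue handling cannot be separated from the driver. Levels are CPM, counts scaled to the library's total reads, given as mean ± SD over the 4 TRH pools. Log2 fold changes are TRH minus sNPFR. The value after their ± is the absolute fold change divided by the square root of the test's F statistic, an approximate standard error. It is worked back from the test and is no separate measure of error. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Intervals and floors cover counting error only.

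The genes behind the driver names were read first, as a check of the labels. Trh, the tryptophan hydroxylase gene (FBgn0035187, chromosome 3L, 1190384 to 1193173, minus strand), stood at 13868 ± 2432 CPM (SD, n = 4) in the TRH pools, with 0 reads in the sNPFR pool and 2 reads in all 8 cells. SerT, the serotonin transporter (FBgn0010414, chromosome 2R, 24404595 to 24411074, minus strand), stood at 3857 ± 1912 CPM, with 0 reads in the sNPFR pool and 2 reads in the cells. Vmat, the vesicular monoamine transporter (FBgn0260964, chromosome 2R, 13513132 to 13534251, minus strand), stood at 49091 ± 11605 CPM and was the most abundant transcript of the TRH pools, with 0 reads in the sNPFR pool and 12 in the cells. All 3 genes were higher in the 4 TRH pools (adjusted p = 0.00148 for Trh, 0.00504 for SerT and 0.00517 for Vmat, edgeR). With limma-voom these 3 calls were lost (adjusted p = 0.437, 0.27 and 0.999). The sNPF-R gene (FBgn0036934, chromosome 3L, 20058511 to 20089007, minus strand) stood at 59.7 ± 57.6 CPM in the TRH pools, 139.7 CPM in the sNPFR pool and 1419 CPM in the summed cells, or 320.3 CPM without cell 7. It was higher in sNPFR (log2 fold change -4.44 ± 1.10, adjusted p = 0.0422), although TRH pool 40, at 145.6 CPM, lay above the sNPFR pool. That call was lost in 13 of 28 alternative settings, among them the sNPFR pool taken alone, where the spread comes from the TRH pools only, and the sum without cell 7 (log2 fold change -2.51, adjusted p = 0.117, edgeR).

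Ddc, the decarboxylase that makes serotonin and dopamine, was found on both sides. It stood at 6596 ± 1076 CPM in the TRH pools, 572.0 CPM in the sNPFR pool and 334.8 CPM in the summed cells (log2 fold change 3.41 ± 0.32, adjusted p = 0.00518). The sum was 611.8 CPM without cell 7 and 215.0 CPM without cell 4, and the call held without either. Of the 7 genes of serotonin synthesis and transport, 5 were higher in TRH, both over all genes and adjusted over the list alone. The fifth was pr, a gene of pterin cofactor synthesis, with 55.3 ± 10.7 CPM and 0 reads in both sNPFR units. Pu and Pcd, also of the cofactor pathway, did not pass, at 380.4 ± 107.8 and 140.2 ± 25.8 CPM in the TRH pools. The list as a whole was higher in TRH by the camera set test (adjusted p = 0.00114), and the adjusted p was 0.472 with an estimated correlation.

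**Figure D1:**
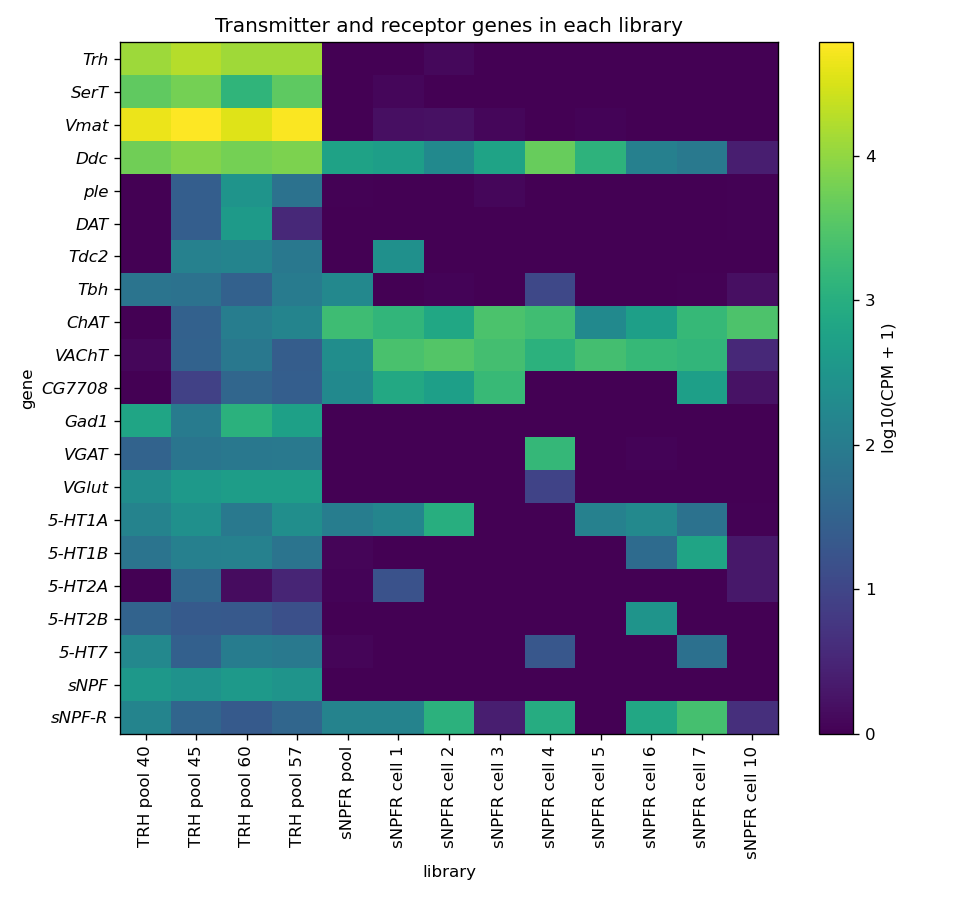
Heat map of log10(CPM + 1) for transmitter and receptor genes (vertical axis) in the 13 libraries (horizontal axis: 4 TRH pools, the sNPFR pool and 8 sNPFR cells). Trh, SerT and Vmat are bright in the 4 TRH pools and near 0 elsewhere, while ChAT is above 10 CPM in the sNPFR pool and in 8 of 8 cells.

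Genes for other transmitters also differed in level. Gad1, which makes GABA, stood at 596.6 ± 428.1 CPM in the TRH pools, from 95.6 to 1136 CPM, and had 0 reads in both sNPFR units (adjusted p = 0.0140, edgeR). Its mean was 11200-fold above the floor of 3 reads in the sNPFR pool. PCR copies count as reads in that floor, so it sets no lower limit on the difference. VGlut, the vesicular glutamate transporter, stood at 380.4 ± 113.0 CPM in the TRH pools, with 0 reads in the sNPFR pool and 27 in the cells (adjusted p = 0.0226). The peptide gene sNPF stood at 323.0 ± 46.1 CPM, a mean 6040-fold above that floor, with 0 reads in both sNPFR units (adjusted p = 0.00504). The cholinergic genes lay the other way but did not pass. ChAT, choline acetyltransferase (chromosome 3R, 18705501 to 18732344, plus strand), stood at 69.7 ± 66.7 CPM in the TRH pools, 1962 CPM in the sNPFR pool and 1594 CPM in the summed cells (log2 fold change -5.16 ± 1.78, adjusted p = 0.106). VAChT, the vesicular acetylcholine transporter, stood at 34.4 ± 33.9, 221.2 and 1490 CPM (adjusted p = 0.0775). The choline transporter CG7708 stood at 17.5 ± 17.0, 189.0 and 404.2 CPM (adjusted p = 0.124). None of these 3 passed over all genes, and 3 of 3 passed adjusted over the list alone. Camera placed the list higher in sNPFR (adjusted p = 0.0170), with adjusted p = 0.472 with an estimated correlation. Over genes at 1 CPM or more in both sNPFR units, a setting chosen after seeing the data, it was 0.126. VAChT lies inside ChAT on the same strand, so reads of this pair are uncertain. The dopamine genes ple and DAT did not pass over all genes, and 2 of 2 passed adjusted over the list alone. Their levels differed between TRH pools, from 0 CPM in pool 40 to 300.7 and 401.4 CPM in pool 60. Tdc2 and Tbh, of tyramine and octopamine synthesis, and VGAT, the vesicular GABA transporter, did not pass either. Nearly all VGAT reads in sNPFR came from cell 4, at 1515 CPM, and the sum without that cell was 0.00796 CPM. VGAT then passed, higher in TRH (log2 fold change 12.48, adjusted p = 0.0208, edgeR). Leaving out the cell that held the gene all but fixes that outcome, so no difference is read from it. Hdc, of histamine synthesis, had 0 reads in all 13 libraries.

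Over all 7426 tested genes, 1009 passed, with 784 higher in TRH and 225 higher in sNPFR, and 2473 had an unadjusted p under 0.05. Of the 784, 755 were under 1 CPM in both sNPFR units and 513 had 0 reads there. The count changed with single TRH pools left out: without pool 45 it was 30, without pool 60 it was 39 and without pool 57 it was 16, against 989 without pool 40. Genes with an unadjusted p under 0.05 fell less, to 2049, 1946 and 1755 without pools 45, 60 and 57. None of the 1009 genes changed sign in these settings. That was nearly fixed in advance, as for 1004 of them all TRH pools lay on one side of both sNPFR units. The kept signs therefore do not tell why the calls were lost. Calls higher in TRH made up 77.7% of the total, 67.3% with singleton pairing and 87.9% with library totals only. The median log2 fold change of all tested genes was 0.67, and 0.41 to 1.28 across those scalings, so fold changes are read relative to it. Of 67 named genes past the threshold, 10 kept the call whichever TRH pool was left out. These were Trh, SerT, Vmat, Ddc, Nplp1, Proc, Fas2, JhI-21, CG9896 and CG5758.

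Among the genes with the largest differences, Fas2, a cell adhesion molecule, stood at 1209 ± 401 CPM in the TRH pools and JhI-21, an amino acid transporter, at 1179 ± 117 CPM, both with 0 reads in both sNPFR units (adjusted p = 0.0027 and 0.00148, edgeR). CG14989 (740.1 ± 424.5 CPM), twit (566.3 ± 316.8 CPM) and CG15537 (453.9 ± 751.0 CPM) were likewise at 0 reads in sNPFR. CG14989 overlaps Gad1 on the opposite strand, and as strand use in counting is not stated, reads in the stretch they share cannot be told apart. In the other direction, CG9896 rose from 59.7 ± 13.6 CPM in the TRH pools to 2572 CPM in the sNPFR pool and 4708 CPM in the summed cells, 2876 CPM without cell 7 (log2 fold change -6.52 ± 0.45, adjusted p = 0.00348). CG43902 (log2 fold change -6.21 ± 0.66), CG5758 (-5.36 ± 0.48) and the protease gene rho (-5.47 ± 0.57) were also higher in sNPFR, as were DIP-epsilon, the transcription factor genes acj6 and Lim3, and CG7131 and CAH13. CG7131 and CAH13 stood at 91.7 and 98.0 CPM in the sNPFR pool but 10.9 and 2.24 CPM in the summed cells, nearly all from cell 5 (0.0417 CPM each without it), and neither passed the filter on low counts without that cell. A 28S ribosomal RNA pseudogene was called higher in sNPFR, with reads that near-identical copies could share. IA-2, of secretory vesicles, was among the 5 most abundant transcripts of the TRH pools at 18024 ± 3088 CPM and was higher there (log2 fold change 1.18 ± 0.29, adjusted p = 0.0394). Atpalpha, the sodium pump subunit, was higher in sNPFR (-0.94 ± 0.19, adjusted p = 0.0266). lncRNA:noe, mt:lrRNA, lncRNA:Hsromega and Argk, also among the most abundant, did not pass.

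Receptor and channel genes were called in both directions. Of 11 tested acetylcholine receptor genes, 4 were higher in sNPFR, none higher in TRH, and 7 did not pass. These were nAChRbeta1 (log2 fold change -2.05 ± 0.24), nAChRalpha7 (-2.28 ± 0.29), nAChRalpha6 (-2.65 ± 0.57) and nAChRalpha2 (-1.65 ± 0.39). nAChRbeta1 stood at 676.6 ± 51.8 CPM in the TRH pools, 2088 CPM in the sNPFR pool and 1840 CPM in the summed cells (adjusted p = 0.010, edgeR). The list median was -0.92 and its mean 0.03, camera placed it higher in sNPFR (adjusted p = 0.00791), and the adjusted p was 0.354 with an estimated correlation. Of 17 voltage-gated and related channel genes, 6 were higher in sNPFR and 11 did not pass, with 8 against 1 adjusted over the list alone. Ih (-2.02 ± 0.26), NaCP60E (-1.93 ± 0.30), eag (-2.36 ± 0.42) and slo (-1.84 ± 0.34) were among the 6. That list had an adjusted p of 0.00537, and 0.354 with an estimated correlation, a median of -0.89 and a mean of 0.09. Camera compares a list with all other genes, many of them absent from sNPFR. Over the 2492 genes at 1 CPM or more in both sNPFR units, neither the acetylcholine receptor nor the channel list passed (adjusted p = 0.437 and 0.126, camera). That setting was chosen after seeing the data. Rdl, a GABA-gated chloride channel (-1.72 ± 0.31), GluClalpha, a glutamate-gated one (-1.86 ± 0.31), KaiR1D (-2.79 ± 0.65) and DopEcR (-2.18 ± 0.46) were higher in sNPFR as well. KaiR1D lost the call without cell 10 (log2 fold change -1.895, adjusted p = 0.102, edgeR). Of 7 octopamine and tyramine receptor genes, 3 were higher in TRH and 4 did not pass. Octbeta1R stood at 279.9 ± 74.5 CPM in the TRH pools, Oct-TyrR at 90.5 ± 38.5 CPM and Octbeta3R at 78.1 ± 31.0 CPM, each with 0 or 1 read in the sNPFR units. Camera gave that list an adjusted p of 0.0228, and 0.354 with an estimated correlation. Dop1R1 (150.2 ± 104.3 CPM) and Nmdar1 (293.8 ± 91.6 CPM) were higher in TRH. None of the 5 serotonin receptor genes passed: 5-HT1A stood at 175.2 ± 77.6 CPM in the TRH pools, 106.8 CPM in the sNPFR pool and 123.8 CPM in the summed cells, 66.6 CPM without cell 2 and 193.0 CPM without cell 7. This hung on single cells for 5-HT7 and 5-HT2B. Higher in TRH, 5-HT7 passed without cell 7 (log2 fold change 6.74, adjusted p = 0.045, edgeR) and 5-HT2B without cell 6 (10.51, adjusted p = 0.030). Those cells held most reads of the genes: the sums fell from 30.9 to 1.03 CPM and from 17.8 to 0 CPM. Taking out the cell that held the gene all but fixes such a pass, so no difference is read from it.

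Neuropeptide genes were higher in TRH or did not pass. Of 20 tested, 6 were higher in TRH and 14 did not pass, and the list had an adjusted p of 0.0140 by camera and 0.354 with an estimated correlation. Proc, the proctolin gene, stood at 1653 ± 750 CPM in the TRH pools with 0 reads in the sNPFR pool and 2 in the cells, and Nplp1 at 1310 ± 734 CPM with 3 reads and 2 reads (adjusted p = 0.00504 for both, edgeR). Mip stood at 200.8 ± 182.7 CPM. Ilp2 and Ilp5, insulin-like peptides, passed (adjusted p = 0.0222 and 0.0470) but differed widely between pools: Ilp5 stood at 15214, 7.08, 70.7 and 2574 CPM in pools 40, 45, 60 and 57, and its call was lost whichever pool was left out. Of 32 tested neuropeptide receptor genes, 10 were higher in TRH, 1 was higher in sNPFR and 21 did not pass. Dh44-R1 (315.1 ± 138.0 CPM), AstA-R1 (205.1 ± 87.5 CPM), CCHa1-R (101.8 ± 75.4 CPM) and PK2-R2 (52.4 ± 24.3 CPM) were higher in TRH, with at most 1 read in the sNPFR units. That list had an adjusted p of 0.00114, and 0.354 with an estimated correlation. Adjusted over the list alone, 6 neuropeptide, 13 neuropeptide receptor, 3 octopamine and tyramine receptor and 1 acetylcholine receptor genes were higher in TRH, and 4 acetylcholine receptor genes and 1 neuropeptide receptor gene higher in sNPFR. Of 6 peptide processing genes only Cadps passed, higher in sNPFR (-1.68 ± 0.44, adjusted p = 0.0482).

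Among 5 tested serotonergic transcription factor genes, zfh2 (215.5 ± 122.6 CPM in the TRH pools) and en (24.3 ± 21.3 CPM) were higher in TRH, Lim3 was higher in sNPFR and 2 did not pass. Of 83 ribosomal protein genes none passed, and of 58 nuclear oxidative phosphorylation genes 2 did, ND-39 (-1.93 ± 0.41) and UQCR-C1 (-1.85 ± 0.40), higher in sNPFR, with 0 adjusted over the list alone. Without cell 7 ND-39 and UQCR-C1 lost the call (adjusted p = 0.127 and 0.092, edgeR). Camera placed both lists higher in sNPFR (adjusted p = 0.00526 and 1.58e-08), with adjusted p = 0.472 for both with an estimated correlation. Fry passed neither (adjusted p = 0.885 and 0.1615). A setting chosen after seeing the data took the 2492 genes at 1 CPM or more in both sNPFR units, at the preset correlation only. There the ribosomal list turned to higher in TRH (adjusted p = 0.000747, camera). The oxidative phosphorylation list did not pass there (adjusted p = 0.788). Heat shock genes had 1 call of 14, Hsp83 (-1.64 ± 0.37), and an adjusted p of 0.0127 by camera, 0.52 with an estimated correlation and 0.936 over those 2492 genes. The near-identical Hsp70 copies could share reads and are uncertain. General neuronal genes had no call of 10 and an adjusted p of 0.0331 by camera, higher in sNPFR, and 0.494 with an estimated correlation. Over those 2492 genes that list turned to higher in TRH and did not pass (adjusted p = 0.437, camera). No call was made among 16 mitochondrially encoded or 6 activity-regulated genes. Of the clock genes cry, and of the sex determination genes tra, passed, both higher in TRH. The only tested antimicrobial gene, AttA, stood at 54.9 ± 24.8 CPM in the TRH pools and at 0 reads in sNPFR.

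Markers of other cell types were present at uneven levels. Of 8 tested glia markers none passed, but the sNPFR pool held Eaat1, a glial glutamate transporter, at 1105 CPM and alrm, an astrocyte gene, at 323.2 CPM, against 87.9 ± 116.4 and 4.74 ± 9.48 CPM in the TRH pools and 0.43 and 0.15 CPM in the summed cells. Of the 11 listed glia markers 7 had 0 reads in that pool, among them repo and nrv2, the latter at 81.4 ± 97.2 CPM in the TRH pools. None of 4 tested muscle markers passed. Pxn, of the hemocyte and basement membrane list, stood at 251.6 ± 115.4 CPM in the TRH pools and 0 reads in sNPFR. Every other gene of that list averaged at most 7.37 CPM in the TRH pools, so no hemocytes are read from Pxn. Of the Kenyon cell markers, toy, ey and prt were higher in TRH and mub was higher in sNPFR. norpA, the only photoreceptor marker tested, was higher in sNPFR (-2.44 ± 0.39). The opsin gene ninaE had 0 reads in all sNPFR libraries, while Arr1 and Arr2 of that list reached 10 CPM in 1 cell each.

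Within the 8 single cells, ChAT reached 10 CPM in 8 of 8 cells (exact Clopper-Pearson interval 63.1% to 100%), from 186.4 to 2843 CPM. VAChT did so in 7 of 8 and CG7708 in 4 of 8. Gad1 had 0 reads in all 8 cells, which allows up to 36.9% of cells with a read and sets no limit on cells expressing the gene, and VGlut stayed under 10 CPM in all 8. VGAT stood at 1515 CPM in cell 4 and under 10 CPM in the other 7. 5-HT1A reached 10 CPM in 5 of 8 cells (24.5% to 91.5%), from 61.6 to 1010 CPM. 5-HT1B and 5-HT7 did so in 2 of 8 each, and 5-HT2A and 5-HT2B in 1 of 8 each. sNPF-R, the gene the driver is named for, reached 10 CPM in 5 of 8 cells (24.5% to 91.5%), up to 2406 CPM, and 4 cells held both sNPF-R and 5-HT1A. Ddc reached 10 CPM in 7 of 8 cells, while Trh, SerT and Vmat did so in none. Of 135 transmitter, receptor and peptide genes, 51 reached 10 CPM in at least 1 cell. Among 34 neuropeptide genes only amn exceeded 100 CPM in any cell, at 210.1 CPM in 1 cell.

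The sNPFR pool and the summed cells were also compared with each other, 1 library against 1 sum and so without a test. Over 4803 genes the median log2 ratio of pool to cells was -0.69. Each of 22 lists was set against 10000 random lists matched on level, as a description of these libraries. Heat shock genes, with a median of 1.21 at the 97.5th percentile, were the 1 list outside the central 95%, where chance gives about 1.1 lists. Near-identical Hsp70 copies in that list could share reads, so no difference between the pool and the cells is read from it.

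At a depth of 3380533 reads for every library, 7167 ± 808 genes (SD, n = 4) had at least 1 read in the TRH pools, 3504 in the sNPFR pool and 2045 ± 656 (SD, n = 8) in the cells. The labels do not give the number of cells of each pool beyond 15 to 60, and do not say whether the numbers in the names of the pools (40, 45, 60 and 57 for TRH, 16 for sNPFR) count cells. Each sNPFR library lay below each TRH pool, with 3504 in the sNPFR pool and 3232 in cell 10 against 6309 in the lowest TRH pool. Many genes of cell 10 had low counts: at 10 CPM or more it had 972 genes, against 784 to 1899 in the other cells. Across genes, the median Spearman correlation was 0.791 between TRH pools, 0.408 between cells, 0.565 between the TRH pools and the sNPFR pool and 0.456 between the sNPFR pool and the cells. Genes are not independent replicates. By Spearman, cells 7 and 10 correlated with the sNPFR pool at 0.732 and 0.796, above the other cells, which lay between 0.359 and 0.459. By Pearson on log2(CPM + 1) they stood at 0.499 and 0.466 and the other cells at 0.353 to 0.468, so cell 10 no longer stood apart.

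**Figure D2:**
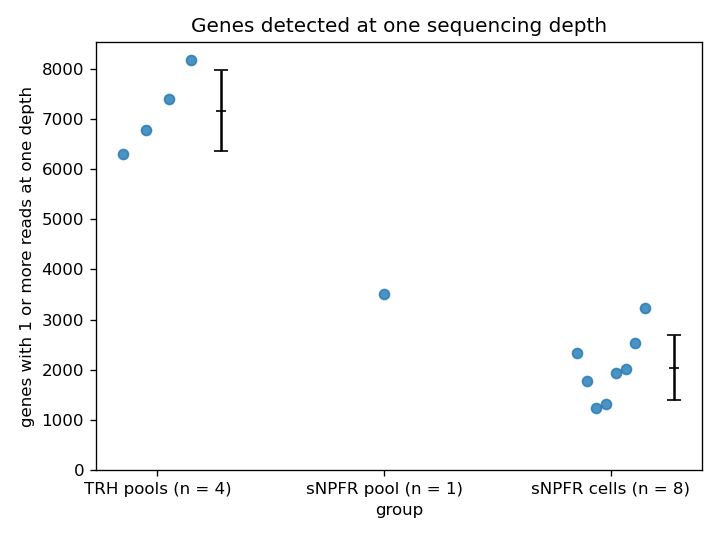
Number of genes with 1 or more reads (vertical axis) after every library was thinned to 3380533 reads, by group (horizontal axis). Points are libraries, and the bars give mean and SD for the TRH pools (n = 4) and the sNPFR cells (n = 8), with TRH pools from 6309 to 8180 genes and sNPFR cells from 1240 to 3232.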

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

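All tests of explanations in this part were chosen after the results were seen. In 45 sets of values, 14 had a library far from the others of its group, where the nominal rate of the rule gives about 2.25. That rate does not allow for the skewed levels of single cells. Some sets are also linked, such as Ilp3 and Ilp5, so no excess over chance is read from the count.

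Among the TRH pools, pool 57 had 15.6 M reads against 8.72 to 9.57 in the others, and 3.35% mitochondrial reads against 1.53% to 1.76%. Trh stood at 17500 CPM in pool 45, against 12310 to 12900 in the others. DAT stood at 401.4 CPM in pool 60, against at most 26.2. sNPF-R stood at 145.6 CPM in pool 40, against 21.9 to 36.4. Ilp3 and Ilp5 stood at 155.2 and 15210 CPM in pool 40, against at most 10.9 and 2574.

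Among the cells, cell 7 had 68.0 M reads against at most 19.2. Cell 4 had 10.6% mitochondrial reads against at most 2.69%, 4.24% ribosomal protein reads against at most 2.05%, 21.1% of reads in its 10 highest genes, and Ddc at 4790 CPM against at most 1265. CG7708 stood at 1690 CPM in cell 3 and 5-HT1A at 1010 CPM in cell 2.

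Sequencing depth is argued against as the reason why most genes called higher in the TRH pools were absent from the sNPFR libraries: the sNPFR pool was the deeper library, and at one depth it had 3504 genes with at least 1 read, against 6309 in the lowest TRH pool. Capture loss needs the absent share to fall with level. The share fell from 6.66% at 100 to 300 CPM to 2.92% at 300 to 1000 CPM (95% interval 1.56% to 4.94%), as capture loss would give. It was 6% at 1000 to 3000 CPM and 20% (5 of 25) above. These 5 genes were Trh, SerT and Vmat, serotonin genes tied to the TRH-Gal4 label, and Ilp5 and CG12239, which were uneven between pools. Placed by the median of the pools, genes from 300 CPM upward gave 2.95%, 4.90% and 3 of 23. Among genes at 300 CPM or more the absent ones lay 0.711 log2 units higher (two-sided permutation p = 0.00284), or 0.477 by the median (p = 0.0401), a test added after Fisher's exact test of genes at 1000 CPM or more against 300 to 1000 CPM gave p = 0.00901 by the mean and 0.102 by the median. Trh, SerT and Vmat were thus absent although 2.92% of genes at the lower level of 300 to 1000 CPM were. The rise itself rests in part on these 3 genes, so it is no separate evidence on why they were absent. No result without these genes is given, so the rise does not decide for other absent genes at 100 CPM or more either. For genes under 100 CPM in the TRH pools, fewer transcripts captured cannot be told apart from a difference between the neurons: 51% of genes at 10 to 30 CPM and 26.5% at 30 to 100 CPM were absent, a fall that capture loss would give, while 0% of 45 ribosomal protein and oxidative phosphorylation genes at 10 to 100 CPM were, against 11.1% to 33.3% in matched sets, and every cell contributes to those genes. The drivers stay open as a biological explanation, confounded with the handling of the brains, and so does the number of cells per pool, which is not given beyond 15 to 60.

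The sNPFR pool and cells 7 and 10 shared many genes at low counts. Reads assigned to the wrong library may be a source. The genes taken stood at 100 CPM or more in 1 of the 3 libraries and under 10 CPM in the other sNPFR libraries. They had no read in the TRH pools. At one depth they had a read in the other 2 in 37.5% of cases, against 1.04% in cells 1 to 6. These 3 libraries were picked from the data because they shared low counts, so the comparison partly restates that observation. If reads were shared, the sNPFR pool and the summed cells are not independent units. The tests would then understate the spread in sNPFR. RNA carried over between the samples was not tested.

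Ilp2, Ilp3 and Ilp5 were each highest in TRH pool 40. A few insulin-producing cells among the sorted cells may be a source, but of the 4 genes listed in advance for such cells 3 were highest in that pool and the fourth, dimm, had 0 CPM there and its highest level, 19.0 CPM, in pool 60, so the test leaves it open. Dsk, added after its values were seen, stood at 428.1 CPM in pool 40. No biological explanation was tested.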

How the results depend on the processing

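Of the alternatives, 3 were chosen after seeing the data: every library thinned to one depth, only genes at 1 CPM or more in both sNPFR units, and cells 4 and 10 left out. No paired analysis was possible because the groups share no replicate numbers.

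None of the 67 named genes past the threshold reversed in the alternatives that tested it, 24 to 28 of 28 per gene and under 28 for 38 genes, but 64 of them lost the call in at least 1, and 10 kept it whichever TRH pool was left out. The count of 1009 genes (784 higher in TRH, 225 in sNPFR) was 3039 (2578, 461) with DESeq2, 2745 (2116, 629) with the sNPFR pool alone, 2027 (1182, 845) with the cells alone, 472 (333, 139) with limma and 10 CPM added, and 151 (72, 79) over shared genes only, where fewer genes are tested. With the pool or the cells alone, 1 unit stands on the sNPFR side and is assumed to vary like the TRH pools, so these counts say nothing of the spread in sNPFR. Genes higher in sNPFR numbered 148 with RLE scaling, 394 with singleton pairing, 117 with totals only, 75 with voom, 135 with thinned cells and 97 with every library thinned. Leaving out 1 library gave 16 to 1226 genes, 10 to 959 higher in TRH and 6 to 267 higher in sNPFR. With cells 4 and 10 left out it was 1131. The cause was not tested.

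The 11 lists past the threshold were 5 with the pool alone, 3 over shared genes (oxidative phosphorylation genes had adjusted p = 0.788 there), 0 with an estimated correlation, and 9 to 12 with 1 library left out. Of lists past the threshold before or after, 3 turned to higher in TRH over shared genes: ribosomal proteins (adjusted p = 0.000747), mitochondrially encoded genes (0.000747), and general neuronal genes (0.437). These are camera values at the preset correlation, and none with an estimated correlation is given for shared genes. Over all tested genes the estimated correlation was 0.066 for ribosomal and 0.658 for mitochondrially encoded genes (adjusted p = 0.472 and 0.981, camera). Shared genes were also chosen by their sNPFR level, with a median log2 fold change of -0.21, so no direction is read from these turns. All 3 lists past the threshold over shared genes were higher in TRH. None of the lists placed higher in sNPFR passed there, with 0.437 for acetylcholine receptors, 0.126 for channels, 0.126 for cholinergic genes and 0.936 for heat shock genes. The count of 51 transmitter, receptor and peptide genes in cells was 88 at 1 read or more, and the cause was not tested. The correlation of TRH pools with the sNPFR pool was 0.531 by Pearson, and that of cells 7 and 10 with the sNPFR pool fell from 0.732 and 0.796 by Spearman to 0.499 and 0.466.

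Of 70 named genes that did not pass, 22 changed sign in at least 1 alternative, 79 values in all, so no direction is read from them; the cause was not tested. Log2 fold changes follow. 5-HT1A (0.094 as reported) was -0.22 with singleton pairing, -0.086 with voom, -0.31 with cells alone, -0.037 with cells 4 and 10 left out, -0.29 to 0.52 with 1 library left out. 5-HT1B (-1.54 as reported) was 1.58 with voom, 8.84 with the pool alone, 1.05 with thinned cells, 2.77 with limma with 1 CPM added, 1.33 with limma with 10 CPM added, -1.81 to 4.29 with 1 library left out. 5-HT2A (3.39 as reported) was -0.22 to 5.59 with 1 library left out. 5-HT2B (0.57 as reported) was -0.54 with cells alone, -0.38 to 10.51 with 1 library left out. Dop2R (0.068 as reported) was -0.28 with singleton pairing, -0.12 with voom, -0.12 with cells alone, -0.23 with thinned cells, -0.089 with limma with 1 CPM added, -0.085 with limma with 10 CPM added, -0.45 to 0.34 with 1 library left out. Eaat1 (-2.98 as reported) was 2.21 with voom, 6.80 with cells alone. GABA-B-R2 (-0.31 as reported) was 0.17 with totals only, 0.27 with all thinned, 0.46 with shared genes only. Hsp70Bb (-0.68 as reported) was 0.12 with shared genes only. Jra (-0.72 as reported) was 0.025 with thinned cells, 0.045 with limma with 1 CPM added, 0.011 with limma with 10 CPM added, 0.059 with shared genes only, -1.24 to 0.027 with 1 library left out. Lcch3 (-0.55 as reported) was 0.11 with all thinned, 0.23 with shared genes only, 0.15 with cells 4 and 10 left out, -1.19 to 0.16 with 1 library left out. Pal2 (0.43 as reported) was -0.13 with cells alone. Pcd (-0.24 as reported) was 0.18 with RLE, 0.43 with totals only, 0.18 with DESeq2, 0.017 with voom, 2.02 with the pool alone, 0.85 with thinned cells, 0.91 with limma with 1 CPM added, 0.81 with limma with 10 CPM added, 0.24 with all thinned, 0.57 with shared genes only, 0.54 with cells 4 and 10 left out, -0.49 to 0.58 with 1 library left out. Syt1 (-0.65 as reported) was 0.14 with shared genes only. Tbh (-0.70 as reported) was 3.48 with voom, 6.48 with cells alone, 1.47 with limma with 1 CPM added, 0.46 with limma with 10 CPM added. VGAT (1.05 as reported) was -0.062 with cells alone, -0.57 with thinned cells, 0.078 to 12.48 with 1 library left out. alrm (-5.28 as reported) was 4.24 with cells alone. apolpp (-1.14 as reported) was 0.85 with cells alone. mt:CoII (-0.50 as reported) was 0.079 with all thinned, 0.25 with shared genes only. onecut (-1.05 as reported) was -1.45 to 0.096 with 1 library left out. per (-5.27 as reported) was 5.02 with the pool alone, 5.46 with cells 4 and 10 left out, -6.37 to 5.47 with 1 library left out. shakB (-0.64 as reported) was 0.15 with cells alone, 0.12 with shared genes only. sr (-0.96 as reported) was 1.81 with voom, 9.29 with the pool alone, 1.16 with thinned cells, 3.59 with limma with 1 CPM added, 2.21 with limma with 10 CPM added, -1.22 to 1.81 with 1 library left out.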

Other observations

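No test is reported in this part, and the genes were singled out after their values were seen. Some peptide transcripts differed widely between TRH pools. Orcokinin stood at 0.11, 1102, 13988 and 5854 CPM in pools 40, 45, 60 and 57, while sNPF ranged from 273.9 to 369.6 CPM. CG12239 stood at 35375 CPM in pool 45 and at 10.2 CPM or less in the others. Dh31 stood at 957.8 CPM in pool 45 and at 8.74 CPM or less in the other TRH pools, and at 158.2 CPM in the sNPFR pool.

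Some transcripts stood high in 1 sNPFR cell and under 1 CPM in the other 7. Tdc2, of tyramine synthesis, stood at 251.7 CPM in cell 1 and 0 CPM in the other 7. VGAT stood at 1515 CPM in cell 4 and at most 0.127 CPM in the others, and cell 4 also held ChAT at 2043 CPM. The clock gene per stood at 3441 CPM in cell 10, at most 0.162 CPM in the others, and averaged 430.2 ± 1217 CPM (SD, n = 8) over the cells.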
